A study of Mus musculus with 16 samples.

How the data were processed

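Cerebella of 8 mice at 3 weeks of age, 4 Npc1-/- and 4 wild type on a BALB/c background, were profiled on Agilent one-colour mouse arrays (500 ng of total RNA per array, labelled with Cy3) and on Illumina bead arrays (200 ng, labelled with biotin), per the labels' protocols. The labels number 4 arrays per genotype on each platform, and groups and replicate numbers were taken from the sample titles. Groups of 4 are small, and p-values measure the spread between these mice. The labels do not state which mouse was hybridised to which array, so each platform was tested by itself, with each array as 1 replicate.

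The Agilent intensity values were deposited as scanner output of Agilent Feature Extraction 9.5, per the submitters' processing notes, and the processed signals were background-subtracted and detrended within each array but not scaled between arrays, per the file headers. Other deposited columns flag spots that are well above background, saturated or outliers, per the file headers. The Illumina intensity values were deposited without normalization, beside a detection p-value for each probe and array, per the file headers. No Illumina software or chip is named in the sources used here. The Illumina table pairs its probe numbers with no gene names, and only 0.349% of the numbers equal a gene identifier in the reference table, so probes were tested and reported by number.

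Agilent spots were processed as log2 of the processed signal minus the array's 75th percentile over all non-control spots, with control spots left out, spots carrying an outlier flag set to missing (74 to 115 per array) and spots of the same probe averaged. No non-control spot was saturated. Probes well above background on at least 4 of the 8 arrays were kept (27164 of 41174). For genes with several probes the probe with the highest mean signal was used, giving 17983 genes. Names were updated through a RefSeq table of mouse assembly GRCm38.p6: 22951 probes matched by accession, 6659 by symbol and 3109 by synonym, and 8455 kept the name in the files. Probe coordinates are those of the files, in the mm7 build; no coordinate of the reference table was used. Illumina signals were processed with limma's neqc (normexp background from detection p-values, offset 16, quantile normalization, log2), and probes with a detection p-value under 0.01 on at least 4 of the 8 arrays were tested (14220). The offset shrinks the fold changes of dim probes.

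Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only factor), with Benjamini-Hochberg adjustment over the genes or probes tested and a threshold of 0.05. Log2 fold changes are Npc1-/- minus wild type. Of 31 gene lists fixed before the data were examined, 28 were tested with limma's camera at its preset inter-gene correlation of 0.01, with the adjusted p taken over the 28 lists; an estimated correlation and the fry test were run beside it. The forebrain and sex-linked lists had fewer than 5 measured members and were not tested, and reference genes were described without a test. Plots were drawn with matplotlib 3.10.9.

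Named genes followed a rule fixed before the data were examined: Npc1; the 15 highest and 15 lowest genes past the threshold whose groups did not overlap (only 6 genes fell); and, per list, up to 4 passing members with the largest change or, where none passed, the 2 members with the highest mean signal. Unnamed transcripts, clones and predicted genes were not ranked, and 2 of the 138 called genes were of that kind. Some genes that the rule takes are not reported here. The rule had planned to rank genes over both platforms; it was applied to the Agilent arrays alone once the Illumina table was seen to hold no gene names, before any fold change was computed.

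The Agilent arrays lay on 4 slides scanned on 2 days, and 3 slides held both genotypes, so fits with the slide or the scan day as a block and differences within slides were computed. Slides 2 and 4 held 1 array of each genotype, and slide 3 held 2 Npc1-/- arrays and 1 wild-type array. Differences within slides, given in that order of slide numbers (2, 3, 4), thus each rest on 1 wild-type array. Slide 1 held wild-type replicate 4 alone, so that array adds nothing to the genotype difference when the slide is a block. Pairwise correlations of arrays over genes ran from 0.969 to 0.994 on Agilent and from 0.961 to 0.99 on Illumina, and no arrays held identical values. The labels give no sex; Xist was well above background on Npc1-/- replicates 2 and 3 and wild-type replicate 2, and the Y-linked gene Ddx3y on the other arrays. The first principal component held 47.0% of the variance on Agilent and 44.4% on Illumina, and on both platforms wild-type replicates 3 and 4 and Npc1-/- replicate 4 lay on one side of it (73.0, 23.0 and 9.71 on Agilent; 33.4, 21.8 and 11.0 on Illumina) and the other arrays on the opposite side (-36.5 to -10.4 and -18.3 to -7.96).

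The fits were tested on simulated data with the spread of the real arrays and 200 changed genes. For the Agilent comparison of 17983 genes, 16% of changes of 0.5 log2 units were recovered, 56% of changes of 1, 90% of changes of 2 and 94% of changes of 3. For the Illumina comparison of 14220 probes, the shares were 56%, 88%, 100% and 100%. The changes were added to each platform's own processed log2 values, and the offset shrinks those of Illumina. The shares therefore do not compare the sensitivity of the platforms. False calls made up 4.48% and 7.03% of all calls, and data without changes gave 0 calls on either platform. The simulated noise was independent between genes and came from a single draw per platform, unlike the variation that genes share on the real arrays. These shares therefore say little about false calls in the real data.

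Alternatives covered the background correction, the normalization, the filter on dim probes, flagged spots, the choice of probe, the variance prior, array weights, blocks, a fold minimum of 1.5 and leaving out each array in turn. Gene names on the Illumina arrays, the Illumina gene lists and the comparison of genes between platforms were not analysed here.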

Results

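Gene expression was measured in the cerebellum of 3-week-old mice with and without a working Npc1 gene. Npc1 encodes a membrane protein that moves cholesterol out of lysosomes, and its loss causes Niemann-Pick disease type C. The labels name 8 mice, 4 of each genotype, and give 4 arrays per genotype on each of 2 platforms, Agilent one-colour arrays and Illumina bead arrays, 16 arrays in all. On the Agilent arrays, 22182 to 28137 of the 41174 probes were well above background, with the lowest number on wild-type replicate 2. On the Illumina arrays, 13658 to 14328 of the 46643 probes had a detection p-value under 0.01. The number of arrays, 4 per group, limits the precision of every comparison. The Illumina table identified probes by number without gene names, so every named gene below was measured on the Agilent arrays.

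The mutated gene was examined first, since its level bears on the sample labels. Npc1 transcript was 3.98-fold lower in Npc1-/- than in wild-type cerebellum (log2 fold change -1.99 ± 0.10 (SE), limma adjusted p = 0.00045). Its signal, in log2 units relative to the 75th percentile of the array, was -2.47 ± 0.12 (SD, n = 4) in Npc1-/- mice and -0.48 ± 0.12 (SD, n = 4) in wild-type mice. The 4 Npc1-/- arrays gave -2.53, -2.44, -2.32 and -2.60, and the 4 wild-type arrays gave -0.52, -0.40, -0.64 and -0.37, so the level parted the arrays as labelled. The probe lies on chromosome 18 at 12540769 to 12540828 in the mm7 build of the file headers; whether that stretch lies inside the part of the gene that the mutation disrupts was not determined here. Another probe assigned to Npc1, at 12569669 to 12569728, was not well above background on any of the 8 arrays. With the slide as a block the log2 fold change of Npc1 was -1.95, and within the 3 slides that held both genotypes it was -1.80, -2.17 and -1.80. Each of these slides held only 1 wild-type array and 1 or 2 Npc1-/- arrays.

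The comparison of the genotypes asked which transcripts change in the cerebellum at this age when Npc1 is missing. Nearly every transcript that passed the threshold was higher in Npc1-/- mice, though the share that was lower varied with the fit, as given below. Of 17983 genes tested, 132 rose and 6 fell (limma, Benjamini-Hochberg adjusted p under 0.05). The glycoprotein Gpnmb, expressed by lipid-laden macrophages, was at least 12.2-fold higher (adjusted p = 0.00045), and it was not well above background on any wild-type array. The lysozyme genes Lyz2 and Lyz1 rose by 3.03 ± 0.19 and 3.00 ± 0.23 log2 units (SE), about 8.20-fold and 8.02-fold, with limma adjusted p of 0.00045 and 0.000878. Their signals moved together from array to array. Whether each probe reads only its own transcript was not tested, so they may not be separate increases.

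Among the 15 genes with the largest fitted increases, the inhibitory receptors Pirb, Cd22 and Cd300lf, the beta-glucan receptor Clec7a and the pore-forming protein Mpeg1 were all higher. Pirb rose 7.44-fold, Clec7a 6.32-fold, Cd300lf 5.37-fold and Mpeg1 4.86-fold (limma adjusted p = 0.00092, 0.00053, 0.00045 and 0.00045). Of the wild-type arrays, 3 measured Pirb above background, 3 Clec7a and 2 Cd300lf. Cd22 was at least 2.60-fold higher (adjusted p = 0.00262). The integrin Itgax rose 9.60-fold (adjusted p = 0.0296), although only 1 of the 4 wild-type arrays measured it above background. The galectin Lgals3 rose 4.79-fold and the chemokine Ccl2, above background on 3 wild-type arrays, 4.72-fold (adjusted p = 0.00053 and 0.0195). Bounds rather than folds apply to genes that no wild-type array measured above background, and they gave at least 3.70-fold for Cxcl10, 2.31-fold for Ccl3, 2.34-fold for the histidine-degrading enzyme Hal and 1.51-fold for the elastase Mmp12. Such a bound sets the mean of the brighter group against, for each array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background.

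The 6 transcripts that fell were Npc1 itself, Pf4, Slc5a11, Slpi, Sp7 and Pycr1. Pf4, the platelet and macrophage chemokine platelet factor 4, fell by 1.81 ± 0.31 log2 units (SE, adjusted p = 0.0423). The sodium-coupled inositol transporter Slc5a11 fell by 1.28 ± 0.14 (adjusted p = 0.0064) and the protease inhibitor Slpi by 1.22 ± 0.17 (adjusted p = 0.0153). The transcription factor Sp7, best known from bone, fell by 1.21 ± 0.21 (adjusted p = 0.0447). The proline-synthesis enzyme Pycr1 fell by 0.86 ± 0.13 log2 units (adjusted p = 0.0289) and was above background on 3 wild-type arrays.

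Every one of the 138 changed genes had all 4 arrays of one genotype above all 4 of the other. Over all tested genes 4.92% were separated in this way, where chance gives 2.86%. With the slide as a block, 38 genes passed, 37 higher and 1 lower. That fit has fewer degrees of freedom, and wild-type replicate 4, alone on its slide, adds nothing to its genotype difference. Whether this loss of precision alone lowered the count was not tested. The number of genes that passed was 65, 60 and 55 without Npc1-/- replicates 1, 2 and 4, and 86 without wild-type replicate 4.

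Of the 36 named genes other than Npc1 that passed, 22 passed in every fit without 1 array that tested them, among them Lyz2, Mpeg1, Trem2, C4b, Oasl2 and Ccl5. Gpnmb, Cd22, Hal and C3ar1, also among the 22, and Cxcl10, Ccl3 and Mmp12 were tested only in the 4 fits that left out a wild-type array, since they fell below the filter without an Npc1-/- array. The other 14 lost their call without at least 1 array. Among fits that left out 1 array, Itgax, C3, Fcrls and Osmr passed only without wild-type replicate 2, with adjusted p up to 0.11, 0.0997, 0.148 and 0.123 otherwise, and Sp7 passed only without wild-type replicate 1, Pycr1 only without Npc1-/- replicate 3 and Itgb2 only without Npc1-/- replicate 3 or wild-type replicate 2 (up to 0.125, 0.111 and 0.104). Pf4 passed only without wild-type replicate 1 or 2 (up to 0.13). Slpi lost its call without Npc1-/- replicate 1, 2 or 3 (up to 0.0605), C1qc without Npc1-/- replicate 1, 2 or 4 (up to 0.0697) and Ccl2 without Npc1-/- replicate 3 or wild-type replicate 3 or 4 (up to 0.0638). Cxcl10 lost it without wild-type replicate 4 (0.0789), and Ccl3 and Mmp12 without wild-type replicate 1, 3 or 4 (up to 0.0967 and 0.127). Of the 36 genes, 16 passed with the slide as a block, such as Lyz2 (3.01), Trem2 (1.47), Oasl2 (1.78) and C1qc (1.37, log2 units), and 20 did not, among them Pf4 (-1.95, adjusted p = 0.0996), Slc5a11 (-1.33, 0.105), Slpi (-1.29, 0.135), C4b (1.93, 0.0866), Icam1 (1.31, 0.0873) and Osmr (0.63, 0.238).

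**Figure D1:**
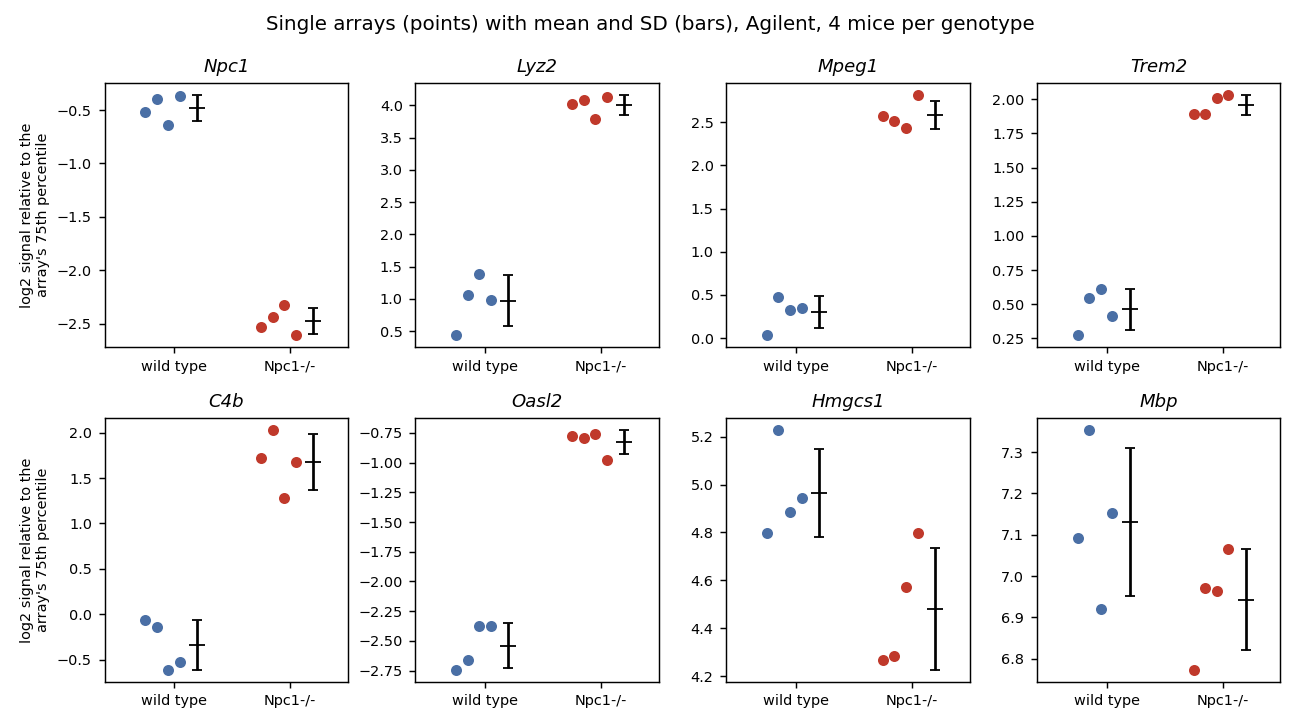
Signals of 8 genes on single Agilent arrays, as log2 signal relative to the 75th percentile of the array (vertical axes, each with its own range), with 4 points per genotype and bars for the mean and SD. Npc1 lies at -2.47 in Npc1-/- and -0.48 in wild-type mice on average, Lyz2, Mpeg1, Trem2, C4b and Oasl2 are higher on every Npc1-/- array, and Hmgcs1 and Mbp differ by -0.48 and -0.19 log2 units.

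Markers of activated microglia and macrophages rose. Of 19 members tested, 13 rose, none fell and 6 did not pass, and 17 were higher when adjusted over the list alone. The median log2 fold change was 2.08, or 1.70 with genes at background in wild type set to their bounds. The 4 members with the largest changes, Gpnmb, Itgax, Lyz2 and Lyz1, were given above. The number that rose was 8 with the slide as a block and 8 without Npc1-/- replicate 1 or 4. The list was shifted by limma's camera test (adjusted p = 1.04e-35, and adjusted p = 0.0171 with an estimated correlation). Its median was 2.01 with the slide as a block and 1.93, 1.38 and 2.11 within slides, and it was 1.18 after normexp background correction with quantile normalization and 1.31 over genes above background on all 8 arrays.

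Of 17 homeostatic microglia markers, 2 rose and none fell (1 with the slide as a block), with 8 higher when adjusted over the list alone and a median log2 fold change of 0.50. Trem2, a lipid-sensing microglial receptor, rose 2.82-fold (limma adjusted p = 0.00053) and the Fc receptor-like gene Fcrls rose 1.87-fold (adjusted p = 0.0423). The list passed camera (adjusted p = 9.06e-10) but not in the stricter form (adjusted p = 0.0883 with an estimated correlation). Its median was 0.52 with the slide as a block, 0.46, 0.66 and 0.50 within slides, and 0.25 after normexp background correction.

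Complement components and Fc receptors rose as a group. Of 12 members, 7 rose and none fell, and all 12 were higher when adjusted over the list alone. The number that rose was 2 with the slide as a block, 1 without Npc1-/- replicate 1, 2 or 4, and 3 without wild-type replicate 4. C4b rose 4.03-fold, C3 2.78-fold and the C1q chain C1qc 2.46-fold, with limma adjusted p of 0.00262, 0.0261 and 0.0153, and the anaphylatoxin receptor C3ar1 was at least 2.43-fold higher (adjusted p = 0.00687). The median log2 fold change of the list was 1.07 (camera adjusted p = 2.46e-23, and adjusted p = 0.0326 with an estimated correlation). It was 1.02 with the slide as a block and 1.09, 0.90 and 1.15 within slides.

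Interferon-stimulated genes were higher as well. Of 21 members, 10 rose and none fell, 19 were higher when adjusted over the list alone, and the median log2 fold change was 1.25. Oasl2 rose 3.28-fold (limma adjusted p = 0.00053), the ISG15 protease Usp18 2.85-fold (adjusted p = 0.00262) and Ifi44 4.24-fold (adjusted p = 0.00738), the last being above background on only 1 wild-type array. The list passed camera (adjusted p = 8.6e-33, and adjusted p = 0.00261 with an estimated correlation). Its median was 1.33 with the slide as a block, 1.29, 1.14 and 1.45 within slides, and 0.67 after normexp background correction.

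Among 15 chemokine and cytokine genes, 6 rose and none fell, with 8 higher when adjusted over the list alone. The members that rose were the chemokines Ccl2, Ccl3, Ccl4, Ccl5, Ccl6 and Cxcl10, with Ccl5, above background on 3 wild-type arrays, 3.77-fold higher (limma adjusted p = 0.00169). The cytokine genes Il1b and Il18, which did not pass, had log2 fold changes of 0.15 and 0.02; they and the full set of chemokines were named after their values were seen. The cytokine genes Tnf, Il6 and Il1a and the chemokines Cxcl1 and Cxcl9 were not among the genes tested. The values of Il1b and Il18 thus do not stand for cytokines in general. The median was 1.01 (camera adjusted p = 1.01e-11, and adjusted p = 0.0394 with an estimated correlation), and 4 of its members also stand in other lists. It was 1.08 with the slide as a block, 0.77, 1.09 and 1.20 within slides, and 0.35 after normexp background correction. It was 0.39, 0.34, 0.40 and 0.20 without Npc1-/- replicates 1, 2, 3 and 4, when chemokines measured only in Npc1-/- mice fell out of the filter and 3 members rose in each fit, and 0.19 over genes above background on all 8 arrays. Without wild-type replicate 4, 2 members rose.

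Of 16 antigen presentation genes, 2 rose, B2m by 2.10-fold and the immunoproteasome subunit Psmb8 by 1.86-fold (limma adjusted p = 0.00623 and 0.00661), and 5 were higher when adjusted over the list alone. Neither passed with the slide as a block (limma adjusted p = 0.0679 and 0.116), although their log2 fold changes were then 1.08 and 0.90, against 1.07 and 0.90 without it. The median log2 fold change was 0.27 (camera adjusted p = 5.16e-07, but adjusted p = 0.193 with an estimated correlation), 0.24 with the slide as a block, 0.13, 0.47 and 0.20 within slides, and 0.15 after normexp background correction. The study's own description names the immune response, steroid and terpenoid synthesis, cell adhesion or motility and lipid transport as changed in these samples, so for lists on those subjects the counts are not independent evidence of direction.

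Astrocyte genes linked to reactivity shifted upward, while general astrocyte markers did not pass. Of 11 reactive astrocyte genes, 1 rose, the oncostatin M receptor Osmr, by 1.56-fold (limma adjusted p = 0.0293), and 5 were higher when adjusted over the list alone. The median log2 fold change was 0.37 (camera adjusted p = 5.42e-08, and adjusted p = 0.0152 with an estimated correlation), 0.30 with the slide as a block and 0.53, 0.20 and 0.35 within slides. Among 12 markers of astrocytes and Bergmann glia, none passed, and the median was 0.06 (camera adjusted p = 0.325). Aldoc and S100b, its most abundant members, had log2 fold changes of 0.00 ± 0.10 and -0.15 ± 0.13 (SE). This list passed under both forms of quantile normalization (adjusted p = 0.0468 after normexp correction, median 0.10, and 0.0252 for the processed signals, median 0.12). Its median was 0.05 with the slide as a block, and within slides 0.11, 0.08 and 0.05.

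Enzymes of cholesterol synthesis had lower values in Npc1-/- mice, without a single gene passing on its own. All 20 members had negative log2 fold changes, from -0.61 to -0.07 with a median of -0.32, yet none passed over all genes, and 8 were lower when adjusted over the list alone. Hmgcs1, the synthase upstream of HMG-CoA reductase, had a log2 fold change of -0.48 ± 0.15 (SE, limma adjusted p = 0.389), with 1 of its 3 probes going the other way, and the sterol isomerase Ebp had -0.26 ± 0.12 (adjusted p = 0.724). The list passed camera (adjusted p = 3.3e-11), but not when the correlation among its genes was estimated (adjusted p = 0.193 with an estimated correlation). Its median was -0.37 with the slide as a block and -0.48, -0.45 and -0.18 within slides, and it was -0.20 without wild-type replicates 2 and 3 together. With array weights, 3 members were lower over all genes. Myelinating oligodendrocyte markers, given here for comparison, were lowest on Npc1-/- replicate 1 and highest on wild-type replicate 2, as was this list. The list medians on Npc1-/- replicates 1 to 4, relative to the mean of all arrays, were -0.38, -0.25, -0.17 and 0.07 for cholesterol synthesis and -0.45, -0.32, -0.30 and -0.02 for myelin, and on wild-type replicates 1 to 4 they were 0.01, 0.34, 0.20 and 0.13 and 0.05, 0.57, 0.15 and 0.28.

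The SREBP and fatty acid synthesis genes, which respond to cellular sterol, had a median log2 fold change of -0.15, with none of 18 passing and none when adjusted over the list alone. Scd2 and Fasn had -0.16 ± 0.10 and -0.14 ± 0.11 (SE). The list's camera call (adjusted p = 0.000304) was lost in the stricter form (adjusted p = 0.231 with an estimated correlation). With the slide as a block its median was -0.14, and within slides it was -0.18, -0.25 and -0.05. Of 23 lipid transport and efflux genes none passed over all genes, 3 were higher when adjusted over the list alone, and the list did not pass (median 0.06, camera adjusted p = 0.0856). Apoe and Fabp7 had log2 fold changes of 0.34 ± 0.12 and -0.59 ± 0.21 (SE), with limma adjusted p of 0.521 and 0.496. The list did pass without wild-type replicate 3 (adjusted p = 0.0316), after either form of quantile normalization (0.0342 and 0.0388), without a filter on dim probes (0.0105) and without wild-type replicates 2 and 3 together (0.0113), and its median was 0.05 with the slide as a block and 0.04, 0.02 and 0.03 within slides. Over genes above background on all 8 arrays its median was -0.02, so the sign was not stable.

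Among 28 lysosomal genes 1 rose, the cathepsin Ctss by 2.22-fold (limma adjusted p = 0.00576), and 3 were higher when adjusted over the list alone. Ctss did not pass with the slide as a block (1.18 log2 units). Cathepsin S is mainly a protease of microglia and macrophages in brain. The median was 0.13 (camera adjusted p = 1.94e-06, but adjusted p = 0.242 with an estimated correlation), 0.15 with the slide as a block and 0.06, 0.18 and 0.20 within slides.

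Genes of myelinating oligodendrocytes had lower values in Npc1-/- mice. Of 24 members, 23 had negative log2 fold changes, with a median of -0.57; none passed over all genes, and 17 were lower when adjusted over the list alone. Mbp, which encodes myelin basic protein, had a log2 fold change of -0.19 ± 0.12 (SE, limma adjusted p = 0.752). The list passed camera (adjusted p = 3.57e-17), but not with an estimated correlation (adjusted p = 0.153 with an estimated correlation), and it passed fry, which asks whether its genes move one way (adjusted p = 0.036). Homeostatic microglia and antigen presentation genes, which also lost the call with an estimated correlation, passed fry too (adjusted p = 0.00712 and 0.0414). Single members passed under some alternatives, 12 of them with array weights, 5 with the brainstem genes as a covariate, 3 with a trended robust prior, 2 after normexp correction and 1 each with quantile normalization, with the scan day as a block and without wild-type replicate 1 or 3. The median was -0.62 with the slide as a block and -0.40, -0.81 and -0.34 within slides. Wild-type replicate 2 had the highest myelin values, with a median 0.57 log2 units above the mean of all arrays.

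Oligodendrocyte precursor genes had a median log2 fold change of -0.22, with none of 9 passing and 3 lower when adjusted over the list alone (camera adjusted p = 0.00923, but adjusted p = 0.361 with an estimated correlation). Gpr17 and Olig1 had values of -0.40 ± 0.12 and -0.38 ± 0.14 (SE). With the slide as a block the median was -0.19, and within slides it was 0.04, -0.56 and -0.16. The call was lost without Npc1-/- replicate 3 (median -0.19, adjusted p = 0.0555) and without wild-type replicate 2 (-0.10, 0.161), and the median was -0.35 without wild-type replicate 1.

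Markers of Purkinje and granule cells had negative medians. Of 15 Purkinje cell genes, 14 had negative log2 fold changes and none passed, with a median of -0.22 (camera adjusted p = 3.04e-05, but adjusted p = 0.231 with an estimated correlation). Itpr1 and Slc1a6, abundant in Purkinje cells, had values of -0.03 ± 0.12 and -0.24 ± 0.13 (SE). All 15 granule cell genes had negative values and none passed, with a median of -0.22 (camera adjusted p = 6.22e-06, but adjusted p = 0.211 with an estimated correlation). Cbln1 and Zic1 had values of -0.21 ± 0.14 and -0.26 ± 0.12 (SE). For both lists none passed when adjusted over the list alone. Without wild-type replicate 3 the Purkinje median was -0.13. It was -0.21 with the slide as a block and -0.59, -0.02 and -0.14 within slides, and the granule cell median was -0.17 and, within slides, -0.31, -0.13 and -0.16. The 7 cerebellar interneuron markers had a median of 0.00 and a mean of 0.03, while camera's direction was downward (adjusted p = 0.785), with Slc32a1 at -0.11 ± 0.11 and Pvalb at -0.29 ± 0.17 (SE).

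Adhesion genes did not shift as a group. Of 25 cell adhesion molecules, 1 rose over all genes and when adjusted over the list alone, the leukocyte ligand Icam1, by 2.46-fold (limma adjusted p = 0.00876), and the median was -0.06 while the mean was 0.02 (camera, downward, adjusted p = 0.488). Its median was -0.05 with the slide as a block and -0.02, 0.00 and 0.03 within slides. Of 27 extracellular matrix and integrin genes, 1 rose, the leukocyte integrin Itgb2, by 2.08-fold (adjusted p = 0.0262), and 2 were higher and 3 lower when adjusted over the list alone. That list had a median of 0.14 (camera adjusted p = 0.0371, but adjusted p = 0.242 with an estimated correlation), and with the slide as a block the call was lost (median 0.14, camera adjusted p = 0.113). Within slides its median was 0.22, 0.01 and 0.08. The call was also lost without Npc1-/- replicates 1, 2 and 4 (adjusted p = 0.0914, 0.0728 and 0.0554) and without wild-type replicates 1 and 4 (0.154 and 0.079), after normexp correction (0.0877), with the mean of probes (0.082), with the scan day as a block (0.0727) and with the brainstem genes as a covariate (0.0894). With the replicate number as a block it was lost too (camera adjusted p = 0.0684).

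Several lists held markers of tissue next to the cerebellum or of other cells. The 8 brainstem genes measured, all Hox genes, had a median log2 fold change of 1.66 with none passing, also when adjusted over the list alone (camera adjusted p = 0.0049, but adjusted p = 0.323 with an estimated correlation). The direction was not shared by the slides, with medians of 3.05, -1.31 and 3.39, and the blocked median was 1.41. Hoxa3 and Hoxc4, the most abundant members, had values of 0.03 ± 0.21 and 0.17 ± 0.15 (SE), and each of the other 6 members was not well above background on 2 or more wild-type arrays (all 4 for Hoxb4), so the size of the list's medians rests in part on background values. The call was lost without Npc1-/- replicate 4 (median 1.19, adjusted p = 0.113) and without wild-type replicate 1 (1.26, 0.0552), and the median was 2.58 without Npc1-/- replicate 1 and 0.43 after normexp correction. Among 9 genes of meninges and fibroblasts none passed, 6 were higher when adjusted over the list alone, and the median was 0.42 (camera adjusted p = 4.83e-05, but adjusted p = 0.193 with an estimated correlation). Igf2 and Col1a2 had values of 0.42 ± 0.15 and 0.57 ± 0.20 (SE), and the median was 0.38 with the slide as a block and 0.29, 0.45 and 0.36 within slides.

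Endothelial genes (10 tested, median -0.01, mean 0.04, camera, upward, adjusted p = 0.527), choroid plexus genes (10 tested, median 0.02, adjusted p = 0.764) and blood cell genes (5 tested, median 0.22, adjusted p = 0.325) did not pass. Cldn5, Enpp2 and Hba-a1 had log2 fold changes of -0.02 ± 0.13, -0.24 ± 0.42 and 0.24 ± 0.28 (SE). When adjusted over the list alone, 1 endothelial gene was higher and no other member passed. The choroid plexus list had medians of 1.07, 0.01 and -1.06 within slides, and without Npc1-/- replicate 3 it passed (median 0.46, adjusted p = 1.08e-05). With the slide as a block, the blood cell list had a camera adjusted p of 0.0496 and a median of 0.08, and without wild-type replicates 2 and 3 together it had 0.037 and 0.43. The median over 3 forebrain neuron genes was -0.18, too few for a list test.

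Of 10 immediate early genes, 9 had positive values and none passed, with a median of 0.42 (camera adjusted p = 0.000375, but adjusted p = 0.214 with an estimated correlation). Nr4a1 and Junb had log2 fold changes of 0.79 ± 0.42 and 0.42 ± 0.16 (SE), the blocked median was 0.35, and within slides the median was 0.22, 0.68 and -0.12. It was 0.86 with array weights and 0.72 with the brainstem genes as a covariate. Of 10 proliferation and granule precursor genes none passed, 1 was lower when adjusted over the list alone, and the median was -0.16 (camera adjusted p = 0.0288, but adjusted p = 0.193 with an estimated correlation). Its call was also lost with the slide as a block (median -0.18, adjusted p = 0.0557), and within slides its median was -0.13, -0.10 and -0.19. Without Npc1-/- replicate 3, Npc1-/- replicate 4 or wild-type replicate 2 the adjusted p was 0.0555, 0.108 or 0.0626, and it was 0.0523 without a filter on dim probes and 0.313 over genes above background on all 8 arrays. Ccnb2 and Mcm5 had values of 0.24 ± 0.25 and -0.35 ± 0.14 (SE). The unfolded protein list (12 tested, median 0.00, camera adjusted p = 0.398) and the oxidative and heat stress list (9 tested, median 0.11, adjusted p = 0.0675) did not pass, with 1 gene higher in each when adjusted over the list alone. The stress list did pass without Npc1-/- replicate 3 (adjusted p = 0.0126) and without wild-type replicate 3 (0.0221), after either form of quantile normalization (0.0374 and 0.0133), without a filter on dim probes (0.0138), over genes above background on all 8 arrays (0.021) and with Xist or the brainstem genes as a covariate (0.0495 and 0.0104). Its median was 0.02, 0.06 and 0.06 without Npc1-/- replicate 1, Npc1-/- replicate 2 and wild-type replicate 1. The 9 reference genes measured had a median of -0.11, and none passed.

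Of the 28 lists tested on Agilent arrays, 19 passed camera with its preset correlation of 0.01, 12 higher and 7 lower. With an estimated correlation 5 passed, all higher: activated microglia and macrophages, complement and Fc receptors, interferon response, chemokines and cytokines, and reactive astrocytes.

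**Figure D2:**
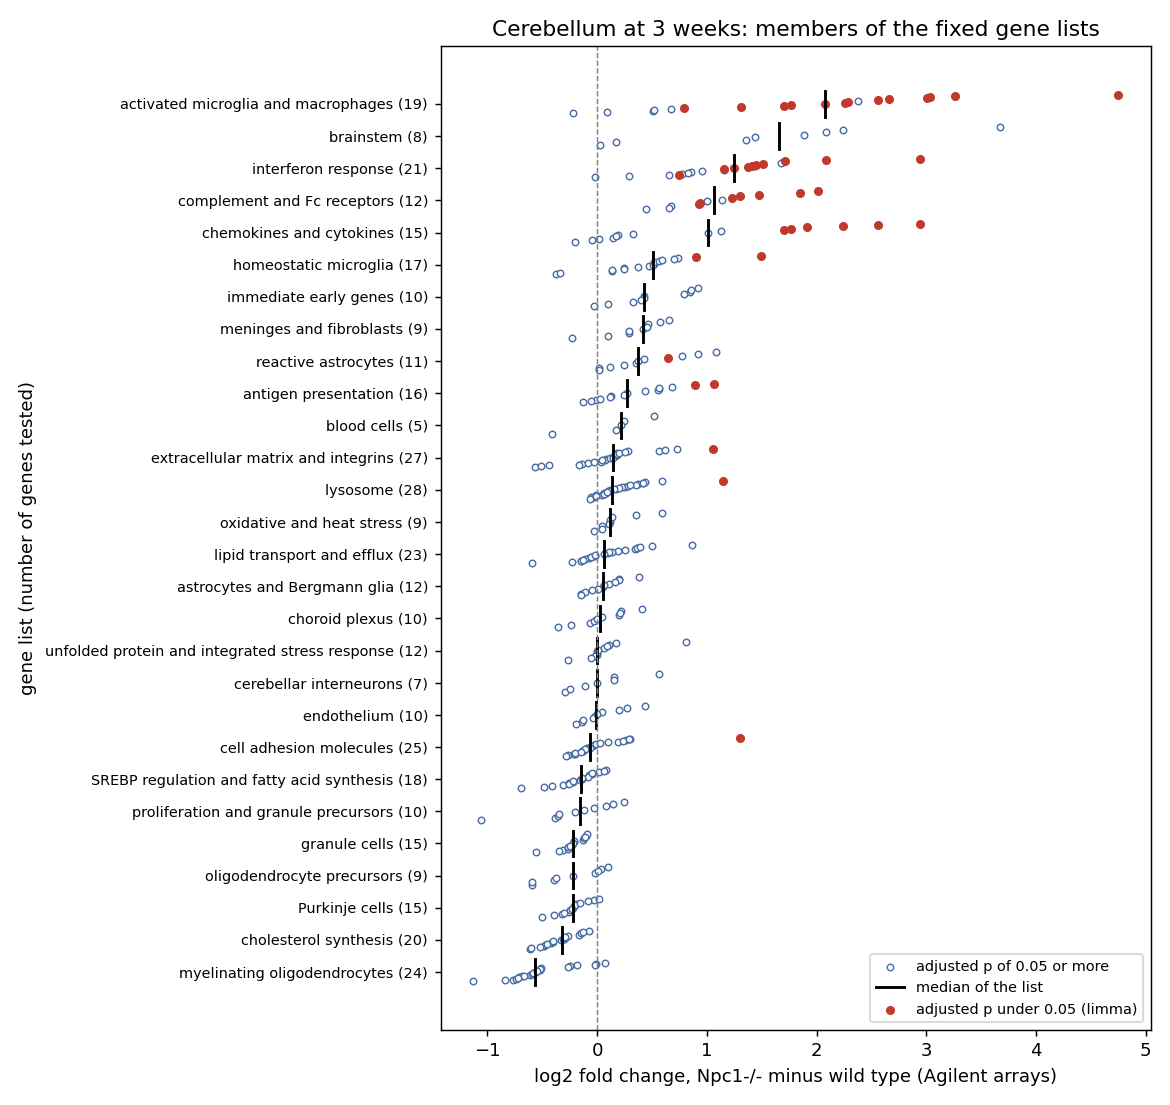
Log2 fold changes (horizontal axis, Npc1-/- minus wild type, Agilent) of the members of each of the 28 gene lists tested (vertical axis, ordered by median), with filled points for genes at an adjusted p under 0.05, open points for the rest and a bar at the list median. The medians run from -0.57 for myelinating oligodendrocytes to 2.08 for activated microglia and macrophages; the brainstem list, at 1.66, has no filled point.

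The Illumina arrays gave the same comparison on a different platform, and the labels name no further mice for them. Of 14220 probes tested, 32 were higher and 4 lower in Npc1-/- mice (limma adjusted p under 0.05). Probe 1780138, not detected on any wild-type array, was at least 8.01-fold higher (adjusted p = 1.93e-05). Probe 6770717, detected on 3 wild-type arrays, rose by 2.99 ± 0.25 log2 units (SE, adjusted p = 0.000581). The probes with the largest decreases, numbers 103940139 and 105690133, fell by 2.11 ± 0.14 and 2.07 ± 0.13 log2 units (SE; adjusted p = 0.000106 and 9.83e-05). All 36 probes had non-overlapping groups, against 4.66% of all tested probes and 2.86% by chance. The count was 11, 10, 11 and 14 without Npc1-/- replicates 1, 2, 3 and 4 in turn, and 21 and 18 without wild-type replicates 1 and 4. Genes shared between the platforms, and Npc1 itself on the Illumina arrays, were not analysed here.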

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

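The tests of blood, of slides and of dilution by other cells were chosen after the results they bear on had been seen, and the fits with Xist or the Hox genes as a covariate were added after the data had been seen but before their own results were; the counts over other splits of the arrays were planned.

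The gene counts were highest for the real genotypes on both platforms, although 1 of 35 splits is the strongest result that 4 against 4 arrays allow. Other splits mix the genotypes, so the genotype difference adds to their spread and lowers their counts. The labels name no further mice for the Illumina arrays, so the counts of the platforms are not independent. Of the 35 splits of the 8 Agilent arrays into 4 and 4, only 1, the real genotypes, gave as many as 138 genes, and the highest of the others gave 2. On the Illumina arrays 1 of 35 splits gave as many as 36 probes, with 3 in the highest other split. The number of gene lists passing with the preset correlation was different: 2 of 35 splits gave as many as the real 19 lists, and the other, also with 19, exchanged Npc1-/- replicate 3 for wild-type replicate 3, so chance was not excluded for that number. With an estimated correlation 1 of 35 splits gave as many as the real 5 lists, and the highest other gave 0.

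Phagocyte and interferon genes were higher in Npc1-/- mice. If blood left in the tissue were the source, haemoglobin should have risen as much as these genes, but the upper 95% bound of its log2 difference was 0.90 (Hba-a1 0.24, Hbb-bt 0.28), below the activated microglia median of 2.08. Within slides of both genotypes the lowest median of that list was 1.38. A negative value could not occur, since 13 of its 19 members passed with non-overlapping groups. The slide block left the list's median near its unblocked value, as given above, but 38 genes passed instead of 138, in a fit with fewer degrees of freedom. With the Xist level as a covariate, which stands for the sex of the mice, the median stayed at 2.08. A response of microglia to the missing Npc1 is a hypothesis that these arrays did not test, and recruited monocytes were not told apart from resident cells.

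The lower values of myelin genes rest on a list whose call was lost with an estimated correlation (adjusted p = 0.153). Brainstem tissue left on the dissected cerebellum could alter myelin content, yet with the mean of the brainstem Hox genes as a covariate the myelin median was -0.76 instead of -0.57. The highest median within a slide of both genotypes was -0.34. On single arrays the list medians were -0.02 or lower in Npc1-/- and 0.05 or higher in wild type. A positive value within a slide was therefore hardly possible, and its sign says little about the slides. Dilution by cells other than astrocytes and endothelium would lower the markers of both as much. Myelin relative to those markers differed between genotypes by -0.57 log2 units (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 arrays allow). These markers were chosen after their medians of 0.06 and -0.01 had been seen, so the difference largely restates the myelin change. Purkinje and granule cell markers, with medians of -0.22 each, were not part of the comparison. Dilution was therefore not excluded. Fewer or less mature oligodendrocytes in Npc1-/- mice remain a hypothesis, beside a difference between litters, which was not tested.

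In 10 of 153 groups of 4 arrays, 1 array lay far from the other 3, measured as its gap to the nearest array over the range of the group; chance gives about 1 in 20. Wild-type replicate 2, the array with the fewest probes above background, was the far array in 4 of them: Itgax (gap share 0.921), Mmp12 (0.913), Slc5a11 (0.961) and Ddx3y (0.968), the last being Y-linked and not above background there. Mmp12 was not above background on any wild-type array. The lowest log2 signal among probes well above background was -3.90 on wild-type replicate 2, against -6.04 to -5.36 on the other arrays. Npc1-/- replicate 4 was the far array for Oasl2 (0.842), Slc32a1 (0.865) and Cldn5 (0.852). The others were Pf4 on Npc1-/- replicate 3 (0.899), Alas2 on Npc1-/- replicate 2 (0.865) and Hspa5 on wild-type replicate 3 (0.933).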

How the results depend on the processing

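Scan day, Xist, the brainstem genes and leaving out wild-type replicates 2 and 3 together were added after seeing the data. Npc1 stayed lower and past the threshold under every alternative run, from -2.06 to -1.69 log2 units. The 138 Agilent genes (132 higher, 6 lower) became 87 (82 higher) with quantile normalization, 59 (56 and 3) without a filter on dim probes, 88 (83 higher) with probes above background on all 8 arrays, and 313 (249 and 64) with array weights. They became 38 (37 and 1) with the slide as a block, 86 (83 and 3) with Xist as a covariate, and 86 (84 and 2) without wild-type replicates 2 and 3 together. The brainstem covariate gave 73 higher and 33 lower, and a trended robust prior gave 12 lower. Leaving out single arrays gave 55 to 148 genes, 52 to 144 higher and 2 to 8 lower. Without 1 of the Npc1-/- arrays, 125 of the 138 genes were still tested, since genes measured only in Npc1-/- mice then fell below 4 arrays; for the other changes the cause was not tested. Under the other normalizations, filters, covariates and blocks, the genes of the 138 that were tested kept their direction; non-overlapping groups fix it when arrays are left out.

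Replicate numbers were not taken to pair the genotypes, since not every pair's deviations correlated positively: they correlated at 0.15, 0.04, -0.45 and 0.20 on Agilent and at 0.32, 0.28, -0.19 and 0.49 on Illumina. Numbers 1 and 2 on Agilent and 1, 2 and 4 on Illumina correlated best with their own number. With the replicate number as a block, 27 Agilent genes passed (26 higher, 1 lower) and 30 Illumina probes (25 higher, 5 lower).

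The 36 Illumina probes (32 higher, 4 lower) became 19 (17 and 2) with detection on all 8 arrays. The lower probes numbered 8 with 75th percentile scaling, 12 with the trended prior and 10 with array weights. Leaving out single arrays gave 10 to 33 probes, 8 to 27 higher and 2 to 6 lower.

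The 19 shifted lists became 5 with an estimated correlation and 8 with fry, and 16 to 21 without single arrays. The estimated correlation gave the highest adjusted p over all alternatives for each called list except proliferation (0.313) and brainstem (0.718). For brainstem the alternatives include the fit with that list's own mean as a covariate, under which its call could not hold. Of 1666 comparisons of named genes with alternatives, 177 lost and 1 gained a call, and no called gene or list reversed. The 1666 include genes without a call in the main fit, which had none to lose. All 177 losses fell on the 36 called genes other than Npc1, so their share of lost calls was larger than 177 of 1666. Not run were the Illumina chip block, the averaging of Illumina probes per gene and every alternative that needs Illumina gene names. No wild-type array measured 13 of the 138 genes above background. Only 76 of the 138 were tested with probes above background on all 8 arrays, so background limits the folds of further genes.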

Other observations

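The tests in this part were chosen after related values had been seen.

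Levels of Hox genes, normally expressed in the hindbrain and spinal cord, differed widely among arrays of each genotype. Hoxb5, in log2 units relative to the 75th percentile of the array, was -5.08, -1.41, -0.26 and 0.15 on Npc1-/- replicates 1 to 4, and -0.12 and -5.51 on wild-type replicates 2 and 4, while it was not well above background on wild-type replicates 1 and 3. Hoxa5 was -3.54, -2.82 and -2.47 on Npc1-/- replicates 2 to 4 and -2.12 on wild-type replicate 2, and it was not well above background on the other arrays. Hoxa3 varied less, from -3.05 to -2.18 over all 8 arrays.

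The Y-linked gene Eif2s3y was not above background on wild-type replicate 4 (-8.05), where Ddx3y (0.03) and Kdm5d (-1.75) were at the level of the other arrays that express them, such as 0.06 and -1.60 on wild-type replicate 1.

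Arrays with the same genotype and number may come from the same mouse on both platforms. Deviations from the genotype means were correlated between all pairs of arrays on each platform, and these pairwise correlations were compared between platforms (r = 0.83). Of 576 relabelings within genotypes, 2 gave as high a value, the labelled one included (exact p = 0.00347, one-sided), and the other was higher by less than the digits printed (0.83). Whatever the numbering, the labels name no mice beyond those of the Agilent arrays. The Illumina results therefore cannot be taken as a test on further animals.

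Pf4 is abundant in macrophages at the borders of the brain, and its lower level could reflect fewer such cells. Of 8 other border macrophage markers none passed and 6 had negative log2 fold changes, with a median of -0.20. limma's camera gave p = 0.136 for these markers, and p = 0.472 with an estimated correlation. Cd163 had -0.92 ± 0.22 (SE) and Clec10a -0.60 ± 0.22, but Stab1 had 0.43 ± 0.13 and Folr2 0.32 ± 0.28. Since the markers went both ways and the list did not pass, the test did not decide whether these cells were fewer. The lower Pf4 level remains unexplained.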
